A study of Mus musculus with 10 samples.

How the data were processed

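RNA of sorted cells from mouse mammary tissue was hybridised to 10 single-colour Affymetrix mouse arrays, from 100 ng of total RNA each per the labels. The deposited table holds log2 values of 22690 probe sets, which the authors made with RMA per the submitters' processing notes. RMA corrects the background, equalises the distributions of the arrays and summarises the probes of a set. Its version is not given, nor whether the 10 arrays were normalized together. The values showed the log2 range of RMA output, with medians of the arrays between 6.89 and 7.02, and were used as deposited.

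Groups and replicate numbers were taken from the sample labels. COF, the fibroblasts of control glands, and CAF, the fibroblasts of tumours, had 3 arrays each, and CSC and TEC, both from tumours, had 2 each. The number of arrays limits the precision. The array annotation gave 20393 probe sets 1 gene symbol, 691 several symbols and 1606 none, and only the first kind was used. Each gene was represented by the probe set with the highest mean over all arrays. This left 12394 genes, of which 12370 matched a RefSeq gene identifier.

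Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with group as the only term and the spread pooled over all 10 arrays. The contrasts were CAF minus COF, CSC minus TEC and CAF minus CSC. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes of a contrast, and a gene passed at an adjusted p under 0.05. Errors given with differences are moderated standard errors, and intervals are 95% confidence intervals. Fibroblast and tumour cell arrays were compared by the mean of CAF and COF minus the mean of CSC and TEC.

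Before the data were examined, 35 gene lists, 88 ligand-receptor pairs, the tests, the other settings to be tried and the rule for naming genes were fixed from textbook knowledge. The 35 lists have 621 distinct genes, of which 566 were measured. Each list was tested with camera at a preset correlation between genes of 0.01, adjusted over the 35 lists of a contrast. Camera with an estimated correlation and fry were run beside it. Camera compares the genes of a list with all others, whereas fry tests whether they move on balance in 1 direction. With an estimated correlation no list was called in any of the 3 contrasts, and 1, 4 and 7 lists had an unadjusted p under 0.05. Camera with the preset correlation called 9, 17 and 19 lists and fry 13, 22 and 34. Where the text gives the test of a called list, both camera values stand beside each other or as ranges. Members of a list were also adjusted over the list alone.

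A ligand-receptor pair counted as split when the ligand was higher in CAF and the receptor in CSC, or the reverse, both at an adjusted p under 0.05. The count was compared with 10000 random assignments of receptors to ligands, one-sided.

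The rule for naming genes took 4 kinds. The first were the 10 greatest increases and the 10 greatest decreases of a contrast among genes that passed and whose arrays did not overlap. The second were up to 4 members of each list with the smallest adjusted p. The others were a fixed set of genes such as Gli1, Shh, Epcam and Wap whatever their values, and members of split pairs. Predicted and unnamed genes were left out. The text names more of them than planned, so that the lists described have examples. Salivary, milk and leukocyte genes named in the tests of other explanations were chosen after their values were seen.

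The pipeline was tested on simulated data of the same size, with 200 changed genes. For changes of 0.5, 1 and 2 on the log2 scale it recovered 28.4%, 79.1% and 98.5% of them between CAF and COF, 19.4%, 62.7% and 95.5% between CSC and TEC, and 20.9%, 70.1% and 92.4% between CAF and CSC. False calls made up 5.52%, 7.09% and 3.17% of all calls. Each simulated gene had the same spread in all groups, and far fewer genes changed than passed in the real data. The real groups differed in spread, with an SD of gene-by-gene differences of 0.55 between the TEC arrays and 0.14 to 0.22 within CAF. These rates thus do not cover groups of unequal spread. The changed list was found and none of 34 unchanged lists was called with either correlation. The simulated genes varied independently, so this could not test lists whose genes vary together. Estimated correlations within the real lists reached 0.84, in the pan-fibroblast list.

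Each result was computed again with only the 2 groups of the contrast, with the replicate number as a block, with a mean-variance trend and robust prior, without the dimmest 30% of genes, and with every probe set tested. Further settings took the mean of all probe sets of a gene, or left out probe sets ending in _x_at or _s_at. It was also computed with a second quantile normalization, with each array centred on its median, with array weights, and at stricter thresholds. Each array was also left out in turn. Of these, the gene lists and ligand-receptor pairs were repeated with the 2 groups, the block, the dim genes left out and each array left out. Settings added after seeing the data averaged the closest arrays, left out COF replicates 2 and 3 together, and left out genes higher in CSC or TEC than in CAF. No gene or array was removed otherwise, and no covariate was added, since the labels give no batch.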

Results

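Gene expression was measured on 10 single-colour Affymetrix mouse arrays, each with RNA of 1 cell population sorted from the mammary gland of FVB/N mice. Fibroblasts of wild-type control glands (COF) and cancer-associated fibroblasts (CAF) had 3 arrays each. The populations sorted from tumours and labelled CSC, for cancer stem cells, and TEC had 2 arrays each. They are called tumour cells here for short. CAF, CSC and TEC came from mammary tumours of mice whose genotype label names a Cre line, a beta-catenin construct and HGF. On the TEC samples 1 label field reads TEFs where the title reads TEC. How the cells were gated is not given in the sources used here. The median value of an array lay between 6.89 and 7.02 on the log2 scale. The 3' minus 5' log2 difference of Actb probe sets, a sign of RNA quality, was 0.32 and 0.46 in TEC, 0.63 and 0.62 in CSC, 0.59 to 0.61 in CAF and 0.66 to 0.76 in COF. The same difference of Gapdh probe sets was 0.26 and 0.24 in TEC and 0.29 and 0.30 in CSC. It was 0.06 to 0.15 in CAF and 0.05 to 0.14 in COF, which overlapped. Both differences thus moved with groups, though in different orders, and their part in the results was not tested. The labels do not say that the arrays come from separate mice, so each p-value measures only the spread between these samples.

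Both fibroblast populations carried fibroblast genes at high levels and tumour epithelial genes at low levels. The 16 pan-fibroblast genes had a median log2 value between 12.91 and 13.05 on the 6 fibroblast arrays, and of 8.34 and 8.40 on the 2 CSC arrays. The 2 TEC arrays differed here, with 8.80 for TEC replicate 1 and 11.42 for TEC replicate 2. The 17 pan-epithelial genes had medians of 11.91 and 11.85 in CSC, 8.98 and 9.34 in TEC, and at most 6.93 in the fibroblast arrays. Leukocyte genes were high in both tumour cell populations. Their median was 13.45 and 13.04 in TEC and 11.33 and 10.78 in CSC, against 5.31 to 7.92 in the fibroblasts. On both TEC arrays the leukocyte median lay above the pan-epithelial median, so the name tumour cells rests on the labels and not on these markers. Between the fibroblast and the tumour cell arrays, 9258 of 12394 genes differed (limma, adjusted p under 0.05), 4967 of them higher in the fibroblasts. All 17 pan-epithelial, 12 leukocyte and 17 macrophage genes were lower in the fibroblasts, and 15 of 16 pan-fibroblast genes were higher.

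**Figure D1:**
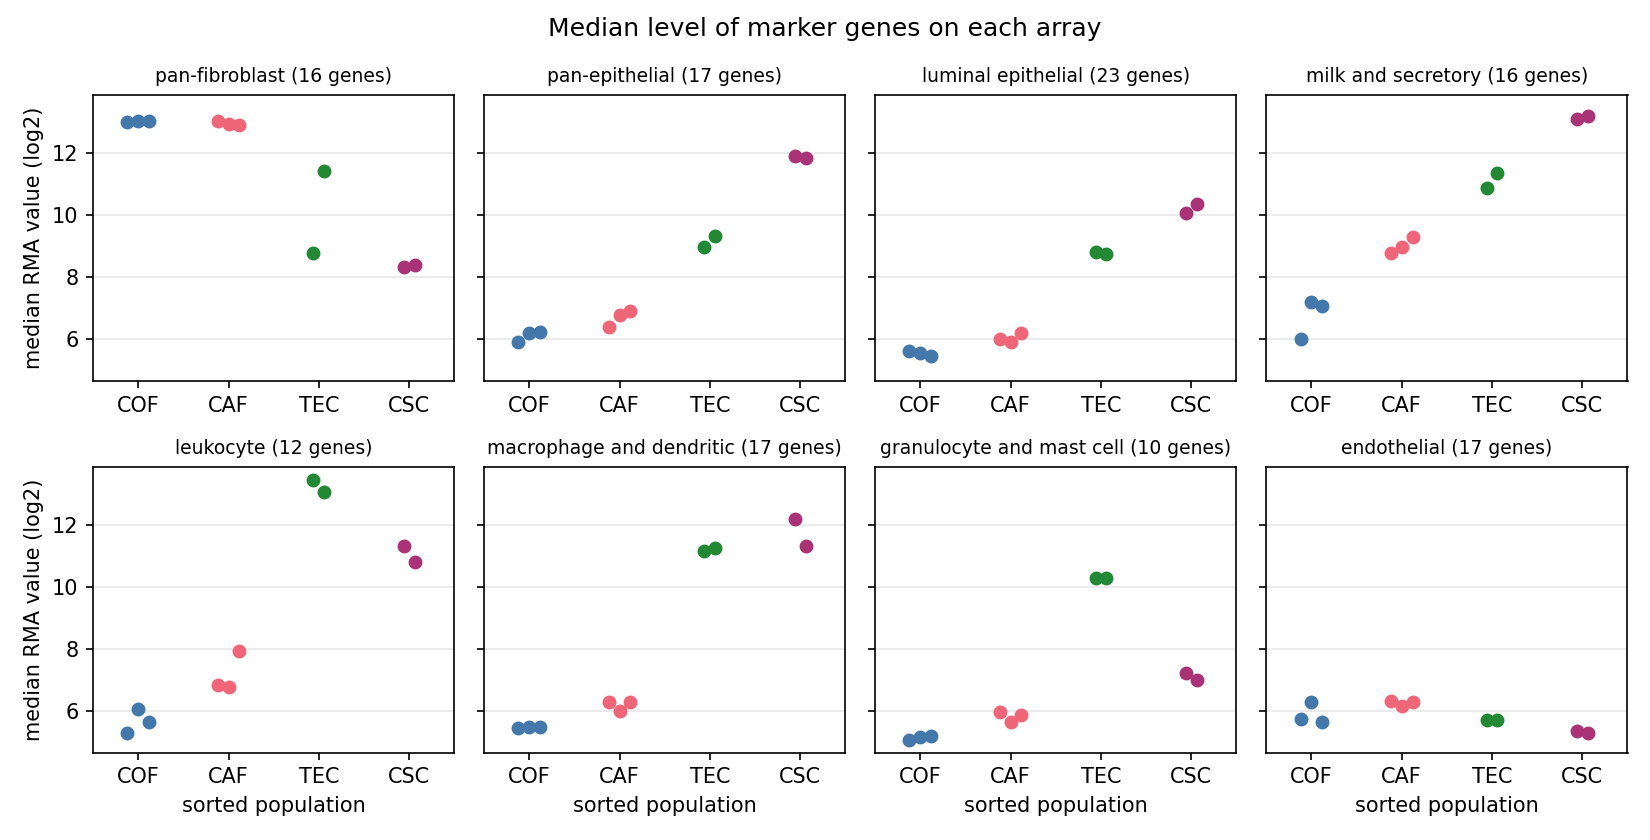
Median log2 value of the genes of 8 marker lists (y axis) in each sorted population (x axis), 1 point per array. TEC replicate 2 had a pan-fibroblast median of 11.42 against 8.80 for TEC replicate 1, and leukocyte medians were above 10 on the 4 tumour cell arrays.

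The comparison of CAF with COF asks how fibroblasts of the tumour differ from those of the healthy gland. CAF carried more transcript of many inflammatory factors, of some contractile and matrix genes, and less of adipocyte regulators, than COF. The acute-phase protein gene Hp was 97.5-fold higher, a log2 difference of 6.61 ± 0.32 (SE, n = 3 and 3, adjusted p = 8.45e-06). Among the other genes with the greatest increases were Ltbp2 (6.51 ± 0.61), a latent TGF-beta binding protein of the matrix, Wif1 (5.58 ± 0.50), a secreted Wnt inhibitor, and Reg3g (5.55 ± 0.33), an antimicrobial lectin, all as log2 difference ± SE. The TNF-family ligand Tnfsf11 (4.86 ± 0.32) and its decoy receptor Tnfrsf11b (4.98 ± 0.59) both rose. The greatest decreases included Inmt (-4.66 ± 0.28), a methyltransferase, Col13a1 (-4.49 ± 0.31), a transmembrane collagen, and the tachykinin precursor Tac1 (-3.37 ± 0.39). Wif1 and Tnfsf11 in COF and Col13a1 in CAF averaged 3.59, 4.38 and 4.69, under the lower quartile of each array, so the size of these differences depends on the background. In all, 4309 of 12394 genes passed the test (limma, adjusted p under 0.05), 2238 higher and 2071 lower in CAF, and 1030 of them differed by at least 1 on the log2 scale.

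Inflammatory factors made up 1 of the groups that rose. Of the inflammatory fibroblast cytokine list, 12 of 22 measured members rose, 1 fell and 9 did not pass (12 and 1 adjusted over the list alone), with camera adjusted p = 6.65e-04, and adjusted p = 0.696 with an estimated correlation. Its members included Lcn2 (4.83 ± 0.23), which sequesters iron carriers of bacteria, Csf3 (3.99 ± 0.31), the granulocyte growth factor, and Saa3 (3.11 ± 0.13), an acute-phase protein (adjusted p of at most 5.11e-05). Lcn2 was higher still in the tumour cells, at a mean of 14.14 in CSC and 14.00 in TEC against 12.21 in CAF. Of the contractile and myofibroblast list, 8 of 17 measured members rose, 1 fell and 8 did not pass (8 and 1 adjusted over the list alone), with camera adjusted p = 0.00575, and adjusted p = 0.582 with an estimated correlation. Smooth muscle actin Acta2 (3.08 ± 0.67), Tagln (3.12 ± 0.54) and Actn1 (2.96 ± 0.25), all parts of the actin cytoskeleton, rose. Acta2 was 7.28, 10.53 and 9.08 on COF replicates 1, 2 and 3. Its probe set is of a type that can hybridise to related genes. Without probe sets of that type, Acta2 differed by 0.25 (adjusted p = 0.163).

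Matrix genes moved in part. Of the collagens and structural matrix list, 8 of 37 measured members rose, 1 fell and 28 did not pass (8 and 1 adjusted over the list alone), and the list as a set was not called (camera adjusted p = 0.274). The members that rose included Col8a1 (4.72 ± 0.50) and the proteoglycan Fmod (3.49 ± 0.52) (adjusted p of at most 0.00101). Of the matrix-remodelling enzymes, 5 of 27 measured members rose, 2 fell and 20 did not pass (5 and 2 adjusted over the list alone) (camera adjusted p = 0.503). The collagenase Mmp13 (3.68 ± 0.47) rose and the plasminogen activator Plau (-1.88 ± 0.27) fell. The fibroblast activation marker Fap (-0.55 ± 0.44, adjusted p = 0.401) passed only in a fit on the 6 fibroblast arrays alone, as lower in CAF (adjusted p = 0.00547), and with array weights. The PDGF receptor Pdgfra did not pass (0.20 ± 0.54, adjusted p = 0.828). Among resting adventitial fibroblast genes, 0 of 17 measured members rose, 4 fell and 13 did not pass (0 and 2 adjusted over the list alone) (camera adjusted p = 0.240), with Gsn (-1.15 ± 0.11) lower. Of the pan-fibroblast list, 1 of 16 measured members rose, 0 fell and 15 did not pass (1 and 0 adjusted over the list alone) (camera adjusted p = 0.875).

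Adipocyte genes fell as a set in CAF. Of these, 0 of 15 measured members rose, 8 fell and 7 did not pass (0 and 8 adjusted over the list alone), with camera adjusted p = 6.35e-04, and adjusted p = 0.582 with an estimated correlation. The adipogenic transcription factors Pparg (-1.87 ± 0.16) and Cebpa (-1.43 ± 0.10) fell, together with lipoprotein lipase, Lpl (-1.07 ± 0.16) (adjusted p of at most 9.98e-04). The adipokine Adipoq fell by 1.36 on the log2 scale ± 0.32 (SE, adjusted p = 0.0103), from a mean of 6.08 in COF, which is between the lower quartile and the median of the array (5.23 and 6.90 on COF replicate 1). In CAF it averaged 4.72, under the lower quartile, so the size of the decrease depends on the background.

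Some Hedgehog, Wnt and TGF-beta genes differed strongly, while their lists as sets did not. The Hedgehog lists were chosen knowing that the study concerns this pathway, so they were not blind to it. The Hedgehog effector Gli1 was 4.18-fold higher in CAF (2.06 ± 0.22, adjusted p = 1.88e-04) and the receptor Ptch1, itself a target of the pathway, 6.33-fold higher (2.66 ± 0.29, adjusted p = 2.24e-04). With the mean of all its probe sets Ptch1 differed by 1.38. The co-receptor Boc (-1.02 ± 0.25) and the transcription factor Foxd1 (-0.57 ± 0.14) fell, the latter with an adjusted p of 0.0502 without COF replicate 3. Foxd1 lay under the lower quartile on every fibroblast array. Gli2 (0.64 ± 0.31, adjusted p = 0.151), Smo (0.14 ± 0.29, adjusted p = 0.770) and Hhip (0.042 ± 0.19, adjusted p = 0.904) did not pass. Gli2 passed in a fit on the 6 fibroblast arrays alone (adjusted p = 0.00134), where Smo and Hhip did not. Of the Hedgehog response list, 2 of 14 measured members rose, 2 fell and 10 did not pass (2 and 2 adjusted over the list alone). Its median (-0.093) and mean (0.19) differed in sign, and camera gave an adjusted p of 0.805. Of the Hedgehog ligands and release genes, 2 of 6 measured members rose, 0 fell and 4 did not pass (2 and 0 adjusted over the list alone) (camera adjusted p = 0.327), with Scube2 (0.72 ± 0.14) and Hhat (0.43 ± 0.12) higher. Hhat had an adjusted p of 0.0599 to 0.0948 when any of COF replicates 1 and 3 or CAF replicates 1 and 2 was left out. The ligands Shh (0.17 ± 0.09, adjusted p = 0.187) and Ihh (0.10 ± 0.10, adjusted p = 0.514) did not pass. Shh averaged 4.17 in COF and 4.34 in CAF, below the lower quartile of every array.

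Of the Wnt/beta-catenin targets, 3 of 19 measured members rose, 1 fell and 15 did not pass (3 and 1 adjusted over the list alone) (camera adjusted p = 0.875; median -0.026 and mean 0.27). Wif1, Ccnd1 (1.93 ± 0.19) and Lgr5 (0.79 ± 0.17) rose and Apcdd1 (-1.53 ± 0.25) fell, and Axin2 did not pass (-0.44 ± 0.20, adjusted p = 0.125). On the 6 fibroblast arrays alone Axin2 passed as lower in CAF (adjusted p = 0.00211). Of the Wnt ligands and secreted modulators, 7 of 22 measured members rose, 3 fell and 12 did not pass (7 and 3 adjusted over the list alone) (camera adjusted p = 0.365). The secreted Wnt antagonists Frzb (2.58 ± 0.14) and Dkk3 (1.51 ± 0.27) rose and the Wnt enhancer Rspo1 (-2.35 ± 0.30) fell. Rspo1 averaged 4.49 in CAF, under the lower quartile of each array, so the size of its decrease depends on the background. The related Rspo2 rose by 0.50 (adjusted p = 0.0253), with values under the lower quartile on every fibroblast array. Of the TGF-beta ligands and response list, 7 of 16 measured members rose, 3 fell and 6 did not pass (7 and 3 adjusted over the list alone) (camera adjusted p = 0.410), with the activin subunit Inhbb (2.51 ± 0.13) higher and Tgfbi (-2.72 ± 0.29) lower. Of the growth factors and BMP antagonists, 4 of 26 measured members rose, 3 fell and 19 did not pass (4 and 3 adjusted over the list alone) (camera adjusted p = 0.826). The BMP ligand Bmp4 (-1.98 ± 0.27) fell and the BMP antagonist Grem1 (1.27 ± 0.17) rose.

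Proliferation genes and markers of other cell types were also higher in CAF. Of the proliferation list, 16 of 24 measured members rose, 1 fell and 7 did not pass (17 and 1 adjusted over the list alone), with camera adjusted p = 0.00500, and adjusted p = 0.696 with an estimated correlation, and 0.0957 with fry. Mki67 (2.14 ± 0.49) rose and Pcna (-1.05 ± 0.084) fell. Mki67 stood at 4.71, 7.17 and 6.14 on COF replicates 1 to 3. Leukocyte genes rose in 10 of 12 measured members (11 adjusted over the list alone), with camera adjusted p = 2.20e-04, and adjusted p = 0.582 with an estimated correlation. Macrophage genes rose in 10 of 17 measured members (10 adjusted over the list alone), with camera adjusted p = 1.32e-04, and adjusted p = 0.582 with an estimated correlation. Granulocyte and mast cell genes rose in 6 of 10 measured members (6 adjusted over the list alone), with camera adjusted p = 0.00575, and adjusted p = 0.582 with an estimated correlation. The rise lay in mast-cell genes such as Cpa3 and Cma1 and in S100a8 and S100a9. Other granulocyte genes had similar means in COF and CAF, with Csf3r at 5.24 and 5.23 and Cxcr2 at 5.19 and 5.21. Elane averaged 4.61 and 4.68, and Mpo 5.41 and 5.59. The pan-leukocyte marker Ptprc went from 5.84 ± 0.69 to 7.76 ± 0.99 (mean log2 value ± SD, n = 3 and 3), and the macrophage gene Lyz2 (3.47 ± 0.32) and the mast-cell protease Cpa3 (2.53 ± 0.29) rose. CAF replicate 3 carried the highest leukocyte median, 7.92 against 6.85 and 6.79. Pan-epithelial genes rose in 9 of 17 measured members (11 adjusted over the list alone), with camera adjusted p = 6.65e-04, and adjusted p = 0.582 with an estimated correlation. Milk and secretory genes rose in 9 of 16 members and fell in 1 (9 and 1 adjusted over the list alone), with camera adjusted p = 0.0149, and adjusted p = 0.582 with an estimated correlation. In a fit on the 6 fibroblast arrays alone the milk list had an adjusted p of 0.0637. The milk protein gene Wap (2.96 ± 0.13) and the epithelial adhesion gene Epcam (1.49 ± 0.31) were among them. Of the 2238 genes higher in CAF, 956 (42.7%) were also higher in CSC or TEC than in CAF, against 41.7% of the 10156 other genes. Without genes higher in CSC or TEC than in CAF, a setting chosen after seeing the data, 2291 genes passed.

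The 2 closest pairs of fibroblast arrays were CAF replicates 1 and 2 and COF replicates 1 and 3. Their log2 values differed gene by gene with an SD of 0.14 and 0.18, against 0.21 to 0.36 for the other pairs within COF or CAF. With each of these pairs averaged, 1805 genes passed, and without COF replicates 2 and 3 it was 2807, both chosen after seeing the data. With averaged arrays Acta2, Adipoq, Boc, Foxd1, Hhat, Lgr5 and Scube2 no longer passed (adjusted p of 0.0511 to 0.159), and array weights, whose estimate did not converge, gave 8632 genes, Axin2, Fap, Gli2, Hhip, Ihh, Shh and Smo among them. In a fit on the 6 fibroblast arrays alone 5686 genes passed.

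**Figure D2:**
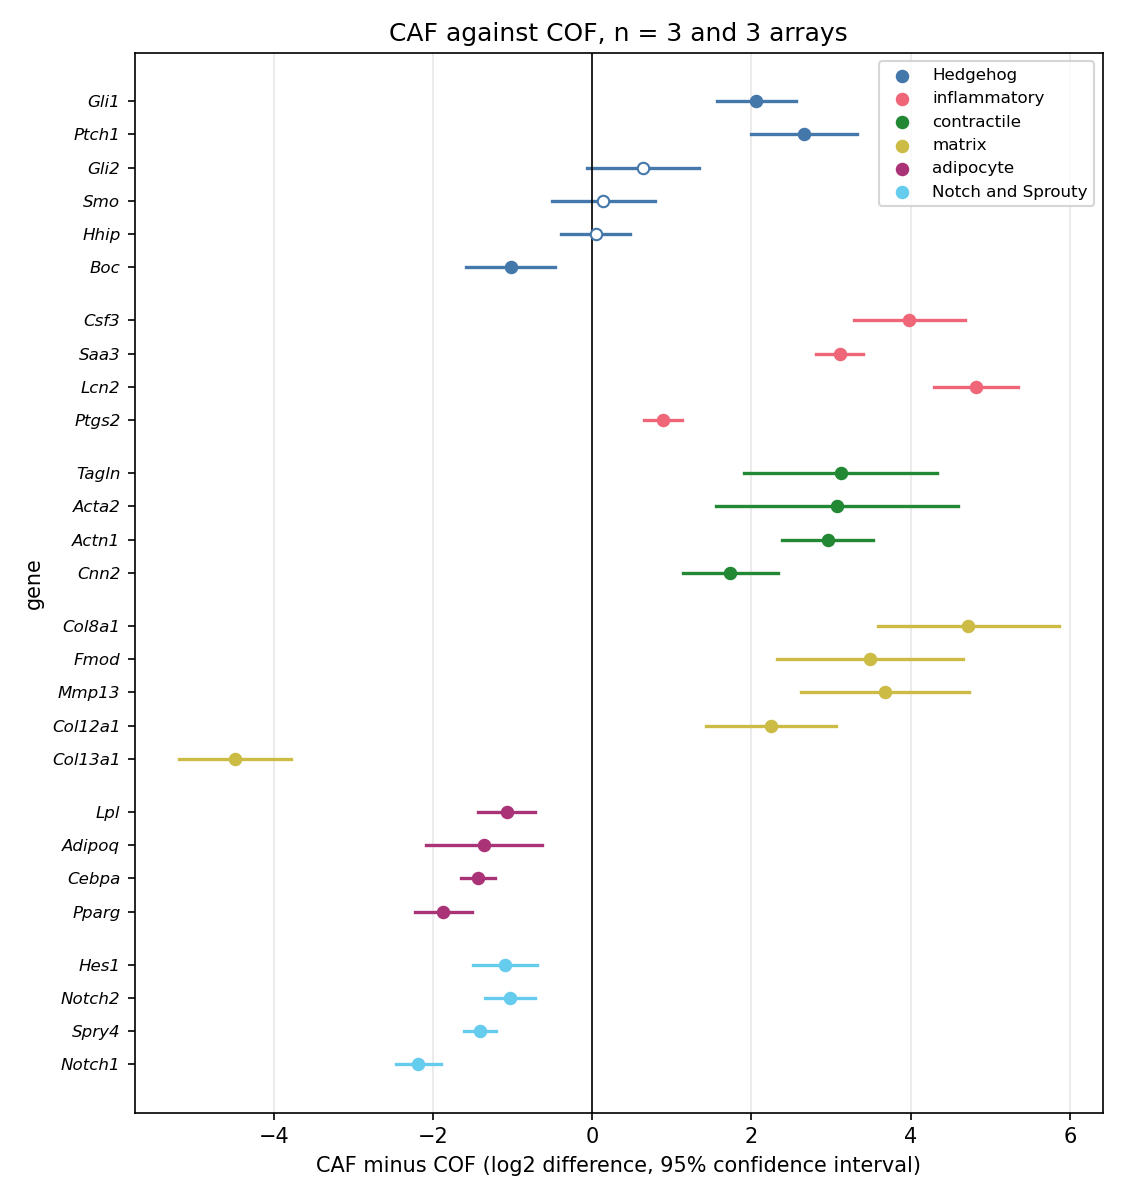
Log2 difference of named genes between CAF and COF (x axis), with gene names on the y axis; points are limma estimates from 3 and 3 arrays, lines 95% confidence intervals, and open points genes that did not pass. Gli1 (2.06) and Ptch1 (2.66) lie to the right of 0 while the intervals of Smo and Hhip include it.

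The comparison of CSC with TEC asks what sets the cells labelled as stem cells apart within the tumour. CSC carried more transcript of both luminal and basal epithelial genes, of milk genes and of some Wnt-related genes, and TEC carried more of leukocyte and fibroblast genes. The pan-epithelial, luminal, basal and milk lists were all higher in CSC, by medians of 2.23, 1.88, 1.75 and 1.38. The shares of cell types on these arrays were not measured. Differences within epithelial cells can thus not be told apart from differences in those shares. Itga6 (2.81 ± 0.26), an integrin used to mark basal mammary cells, Epcam (2.40 ± 0.38), Cldn3 (2.45 ± 0.14) and the epithelial transcription factor Grhl2 (2.35 ± 0.11) were higher in CSC (log2 difference ± SE, n = 2 and 2, adjusted p of at most 7.78e-04). With the mean of all its probe sets Grhl2 differed by 0.43. The basal keratins Krt5 (2.35 ± 0.29) and Krt14 (2.05 ± 0.31) and the luminal keratins Krt8 (2.12 ± 0.43) and Krt18 (2.21 ± 0.47) were all higher as well. The surface marker Cd24a was near 13.59 in CSC and 13.33 in TEC (0.26 ± 0.22, adjusted p = 0.367), and Itgb1 did not pass (0.15 ± 0.14, adjusted p = 0.424). In all, 5786 of 12394 genes passed the test (limma), 3300 higher and 2486 lower in CSC, and 2377 differed by at least 1 on the log2 scale.

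All 4 epithelial lists were higher in CSC. Of the pan-epithelial genes, 16 of 17 measured members were higher in CSC, 0 were lower and 1 did not pass (16 and 0 adjusted over the list alone), with camera adjusted p = 8.26e-08, and adjusted p = 0.350 with an estimated correlation. Of the luminal genes, 14 of 23 measured members were higher in CSC, 0 were lower and 9 did not pass (15 and 0 adjusted over the list alone), with camera adjusted p = 9.51e-05, and adjusted p = 0.350 with an estimated correlation. Of the basal/myoepithelial genes, 11 of 19 measured members were higher in CSC, 0 were lower and 8 did not pass (11 and 1 adjusted over the list alone), with camera adjusted p = 0.00411, and adjusted p = 0.561 with an estimated correlation, and 0.0784 without the dimmest 30% of genes. Of the milk and secretory genes, 10 of 16 measured members were higher in CSC, 0 were lower and 6 did not pass (10 and 0 adjusted over the list alone), with camera adjusted p = 6.80e-05, and adjusted p = 0.350 with an estimated correlation. The milk-fat protein Btn1a1 (3.36 ± 0.17), the lactose synthase subunit Lalba (2.80 ± 0.13) and Wap (2.04 ± 0.16) were higher, while Csn2 was 14.65 in CSC and 14.00 in TEC (0.66 ± 0.99, adjusted p = 0.620; 0.0390 with only the 4 arrays of CSC and TEC). Other large differences were Ttpa (3.72 ± 0.31), which carries vitamin E, and Pigr (3.40 ± 0.28), which carries antibodies across epithelium. The salivary secretory gene Bpifa2 (4.89 ± 1.22) was higher in CSC too, and differed between the 2 CSC arrays (9.17 and 11.61). It did not pass without CSC replicate 2 (3.68, adjusted p = 0.0794) or TEC replicate 1 (3.04, adjusted p = 0.0511).

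Of the Wnt/beta-catenin targets, 6 of 19 measured members were higher in CSC, 1 was lower and 12 did not pass (6 and 1 adjusted over the list alone) (camera adjusted p = 0.127). The feedback inhibitors Axin2 (1.20 ± 0.24) and Rnf43 (2.20 ± 0.23), the transcription factor Sox9 (2.74 ± 0.28) and the cyclin Ccnd1 (2.22 ± 0.23) were higher in CSC (adjusted p of at most 0.00341). Axin2 differed by 0.73 without CSC replicate 2. Cd44 (-1.26 ± 0.14) was lower and Lgr5 did not pass (0.16 ± 0.21, adjusted p = 0.571). Hgf, which the genotype label names, was 6.53-fold higher in CSC (2.71 ± 0.19, adjusted p = 1.30e-05); its receptor Met did not pass (0.41 ± 0.24, adjusted p = 0.189). Of the Met and MAPK response genes, 5 of 13 measured members were higher in CSC, 1 was lower and 7 did not pass (6 and 1 adjusted over the list alone) (camera adjusted p = 0.0909), with Phlda1 (1.55 ± 0.16) and Epha2 (1.14 ± 0.20) higher. Of the mammary stem cell associated genes, 7 of 22 measured members were higher in CSC, 3 were lower and 12 did not pass (7 and 3 adjusted over the list alone) (camera adjusted p = 0.695); Sox9 and Sox10 (1.95 ± 0.13) were higher. Of the Hedgehog response genes, 3 of 14 measured members were higher in CSC, 1 was lower and 10 did not pass (3 and 1 adjusted over the list alone) (camera adjusted p = 0.755), with Boc (1.66 ± 0.30) and Smo (1.09 ± 0.35) higher and Gli1 (-0.99 ± 0.27) lower. Shh was lower by a small amount (-0.38 ± 0.11, adjusted p = 0.0193) at a level of 4.24 and 4.62, below the lower quartile of the arrays. Smo, Gli1 and Shh did not pass without CSC replicate 2 (adjusted p = 0.0907, 0.0792 and 0.119). Smo was also lost without TEC replicate 1 (0.39, adjusted p = 0.0589) or CSC replicate 1 (0.101), and Shh without TEC replicate 2 (0.0668). Without TEC replicate 2 Gli1 differed by -0.49 and Smo by 1.79, and without TEC replicate 1 Gli1 differed by -1.49. Fry, which does not compare a list with other genes, called the Wnt target list as higher in CSC (fry adjusted p = 0.00612). It also called the Met and MAPK list (4.33e-04) and the mammary stem cell list (0.0207) as higher, but not the Hedgehog response list (0.218).

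Genes of leukocytes were higher in TEC. Of the leukocyte genes, 0 of 12 measured members were higher in CSC, 12 were lower and 0 did not pass (0 and 12 adjusted over the list alone), with camera adjusted p = 2.79e-05, and adjusted p = 0.543 with an estimated correlation. Of the granulocyte and mast cell genes, 0 of 10 measured members were higher in CSC, 10 were lower and 0 did not pass (0 and 10 adjusted over the list alone), with camera adjusted p = 1.63e-05, and adjusted p = 0.350 with an estimated correlation. Of the T, NK and B cell genes, 0 of 14 measured members were higher in CSC, 9 were lower and 5 did not pass (0 and 10 adjusted over the list alone), with camera adjusted p = 5.52e-04, and adjusted p = 0.350 with an estimated correlation. The neutrophil collagenase Mmp8 (-5.65 ± 0.43), the B-cell coactivator Pou2af1 (-5.38 ± 0.42) and the chemokine receptor Cxcr2 (-4.78 ± 0.42) had differences among the greatest, though Pou2af1 averaged 3.96 in CSC, under the lower quartile of the arrays. Macrophage genes split, for 4 of 17 measured members were higher in CSC, 7 were lower and 6 did not pass (4 and 8 adjusted over the list alone) (camera adjusted p = 0.239), with the complement gene C1qa (1.61 ± 0.26) higher in CSC and the integrin Itgam (-2.31 ± 0.34) lower. Of the interferon response genes, 0 of 19 measured members were higher in CSC, 10 were lower and 9 did not pass (0 and 10 adjusted over the list alone), with camera adjusted p = 0.00408, and adjusted p = 0.574 with an estimated correlation.

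Fibroblast and mesenchymal genes were also higher in TEC, and TEC replicate 2 carried more of them than TEC replicate 1. Of the resting adventitial fibroblast genes, 0 of 17 measured members were higher in CSC, 12 were lower and 5 did not pass (0 and 13 adjusted over the list alone), with camera adjusted p = 6.80e-05, and adjusted p = 0.574 with an estimated correlation. Of the epithelial-mesenchymal transition genes, 1 of 12 measured members was higher in CSC, 8 were lower and 3 did not pass (1 and 11 adjusted over the list alone), with camera adjusted p = 6.70e-04, and adjusted p = 0.350 with an estimated correlation. Of the pan-fibroblast genes, 0 of 16 measured members were higher in CSC, 7 were lower and 9 did not pass (0 and 13 adjusted over the list alone), with camera adjusted p = 6.76e-04, and adjusted p = 0.621 with an estimated correlation. The fibroblast genes Pi16 (-3.40 ± 0.26) and Igfbp6 (-3.49 ± 0.17) and the mesenchymal regulator Zeb1 (-2.86 ± 0.16) were lower in CSC. Of the collagens and structural matrix genes, 1 of 37 measured members was higher in CSC, 13 were lower and 23 did not pass (1 and 4 adjusted over the list alone), with camera adjusted p = 1.95e-04, and adjusted p = 0.621 with an estimated correlation. Of the matrix-remodelling enzymes, 0 of 27 measured members were higher in CSC, 10 were lower and 17 did not pass (0 and 9 adjusted over the list alone), with camera adjusted p = 8.10e-04, and adjusted p = 0.621 with an estimated correlation. Of the inflammatory fibroblast cytokines, 0 of 22 measured members were higher in CSC, 11 were lower and 11 did not pass (0 and 11 adjusted over the list alone), with camera adjusted p = 0.00408, and adjusted p = 0.621 with an estimated correlation. Without TEC replicate 2 the adjusted p was 0.0506 for the collagens, 0.165 for the enzymes, 0.148 for the cytokines and 0.0620 for the interferon response. Leaving that array out took the median log2 difference of the collagens from -1.46 to -0.29, of the enzymes from -1.22 to -0.29 and of the cytokines from -0.79 to -0.43. For the pan-fibroblast genes it took the median from -1.69 to -0.36 and for the resting fibroblast genes from -1.92 to -0.66. Most of the matrix difference thus lay in 1 array. With fry the collagens had an adjusted p of 0.0719. With only the 4 arrays of CSC and TEC, 3013 genes passed in place of 5786, and Axin2, Boc, Bpifa2, Epha2, Gli1, Shh and Smo were no longer among them (adjusted p of 0.0522 to 0.176).

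**Figure D3:**
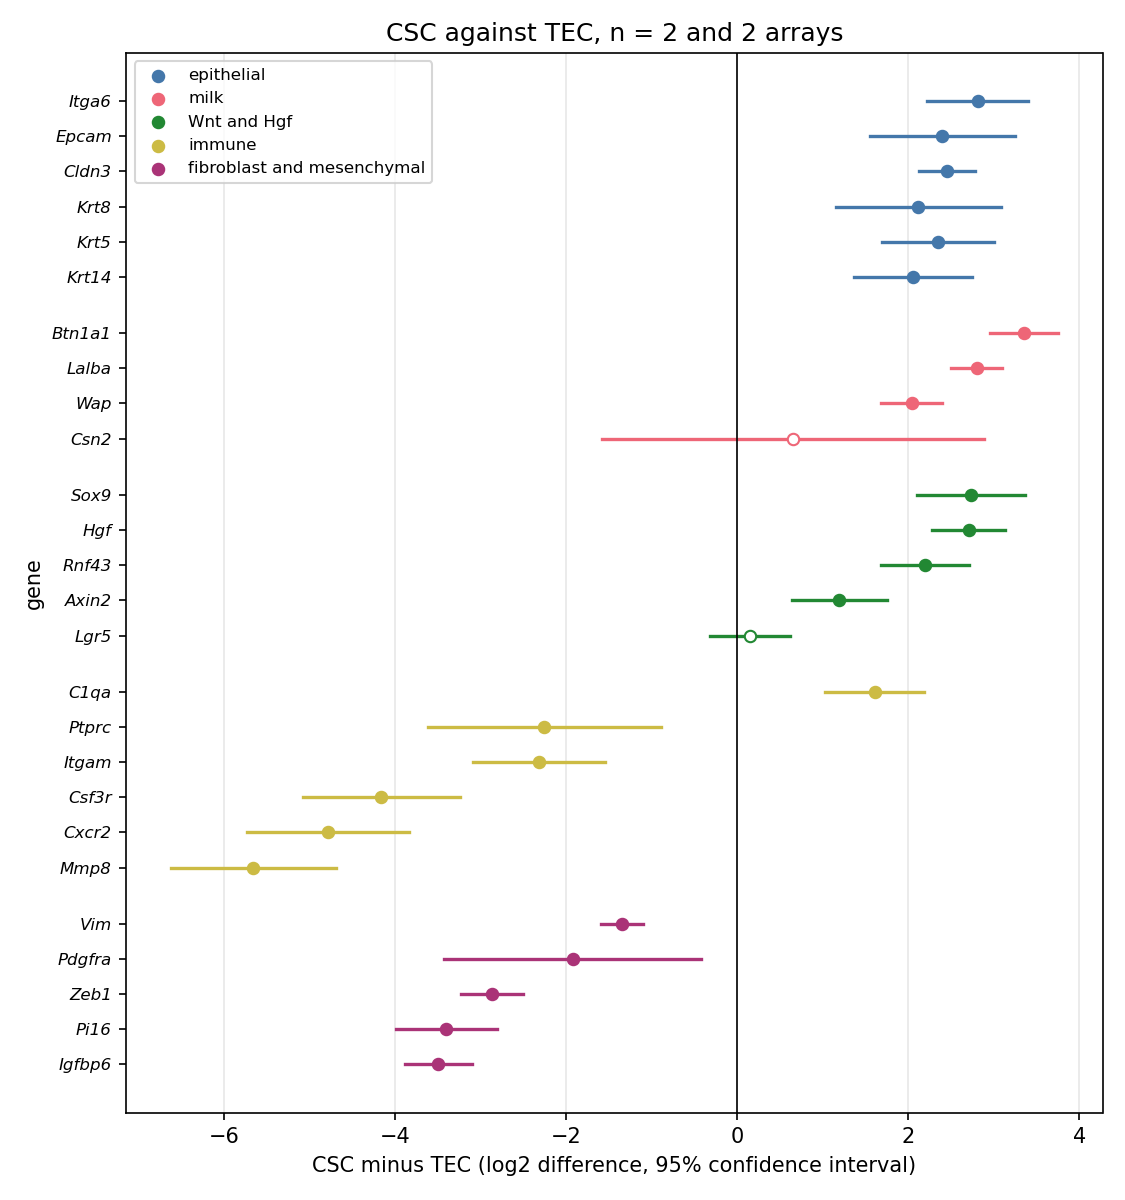
Log2 difference of named genes between CSC and TEC (x axis), with gene names on the y axis; points are limma estimates from 2 and 2 arrays, lines 95% confidence intervals, and open points genes that did not pass. Epithelial genes lie to the right of 0, and Mmp8 (-5.65) and Igfbp6 (-3.49) to the left.

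The comparison of CAF with CSC asks which signals and receptors lie on which side of the tumour. CAF carried far more transcript of fibroblast, matrix and Hedgehog response genes, and CSC more of epithelial, milk, proliferation and macrophage genes. The transcription factor Ebf1 (6.55 ± 0.32), the oxysterol hydroxylase Cyp7b1 (6.46 ± 0.60), the PDGF receptor Pdgfra (6.06 ± 0.61) and the apolipoprotein Apod (6.04 ± 0.53) were among the most different towards CAF (log2 difference ± SE, n = 3 and 2, adjusted p of at most 2.71e-05). Ebf1 averaged 3.84 in CSC, under the lower quartile of each array, and so did Mrc1, Gjb6 and Il10 in CAF (4.05, 3.98 and 3.85), so the size of these differences depends on the background. The macrophage mannose receptor Mrc1 (-7.13 ± 0.20), the gap junction gene Gjb6 (-7.04 ± 0.33), the cytokine Il10 (-6.40 ± 0.19) and the milk gene Lalba (-5.53 ± 0.12) were far lower in CAF. Epcam (-5.41 ± 0.34) and Cd24a (-5.41 ± 0.20) were lower in CAF as well. In all, 8247 of 12394 genes passed the test (limma), 4145 higher in CAF and 4102 lower, and 3417 differed by at least 1 on the log2 scale.

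Of the Hedgehog response genes, 11 of 14 measured members were higher in CAF, 0 were lower and 3 did not pass (12 and 0 adjusted over the list alone), with camera adjusted p = 0.00130, and adjusted p = 0.226 with an estimated correlation. Gli1 (3.41 ± 0.25), Gli2 (3.44 ± 0.35), Hhip (2.41 ± 0.21), Ptch1 (1.87 ± 0.33) and Smo (1.45 ± 0.32) were higher in CAF (adjusted p of at most 0.00318). Hhip was 3.75 and 3.41 on the CSC arrays, under their lower quartiles, and Gli1, at 5.20 and 5.03, lay near them. The size of these 2 differences thus depends on the background. Control fibroblasts shared much of the excess of these Hedgehog genes over CSC. On the COF arrays Gli2 stood at 8.84 to 8.88, Hhip at 5.86 to 6.07 and Smo at 9.55 to 9.87. In CSC Gli2 was 6.26 and 5.86, and Smo 8.41 and 8.32. Gli1, at 6.44 to 6.49 in COF, lay between CSC and CAF, while Ptch1, at 7.37 to 7.54, lay below CSC (8.05 and 8.44). The list result thus does not set CAF apart from other fibroblasts, and COF was not tested against CSC. Of the Hedgehog ligands and release genes, 4 of 6 measured members were higher in CAF, 0 were lower and 2 did not pass (4 and 0 adjusted over the list alone) (camera adjusted p = 0.0816). Fry, which called 34 of the 35 lists in this contrast, called this list as higher in CAF (fry adjusted p = 1.15e-04). Shh averaged 4.34 in CAF and 4.24 in CSC and did not pass (0.10 ± 0.10, adjusted p = 0.419). Of the Wnt ligands and secreted modulators, 14 of 22 measured members were higher in CAF, 2 were lower and 6 did not pass (14 and 2 adjusted over the list alone), with camera adjusted p = 0.00611, and adjusted p = 0.397 with an estimated correlation. Sfrp4 (5.08 ± 0.34) and Sfrp1 (4.51 ± 0.53), secreted Wnt antagonists, were higher in CAF and the ligand Wnt10a (-3.29 ± 0.20) was lower. Axin2 was lower in CAF (-1.89 ± 0.22), as was Hgf (-2.91 ± 0.17). Of the growth factors and BMP antagonists, 17 of 26 measured members were higher in CAF, 5 were lower and 4 did not pass (17 and 5 adjusted over the list alone), with camera adjusted p = 0.0115, and adjusted p = 0.418 with an estimated correlation. Of the collagens and structural matrix genes, 36 of 37 measured members were higher in CAF, 0 were lower and 1 did not pass (36 and 0 adjusted over the list alone), with camera adjusted p = 8.59e-10, and adjusted p = 0.397 with an estimated correlation. Of the proliferation genes, 1 of 24 measured members was higher in CAF, 18 were lower and 5 did not pass (1 and 18 adjusted over the list alone), with camera adjusted p = 0.00118, and adjusted p = 0.474 with an estimated correlation. All 17 macrophage genes were lower in CAF (camera adjusted p = 8.59e-10, and adjusted p = 0.226 with an estimated correlation), and so were all 12 leukocyte genes (camera adjusted p = 1.86e-05, and adjusted p = 0.397 with an estimated correlation). All 16 pan-fibroblast genes were higher in CAF (camera adjusted p = 4.46e-06, and adjusted p = 0.397 with an estimated correlation). All 17 pan-epithelial genes (camera adjusted p = 2.26e-10, and adjusted p = 0.226 with an estimated correlation) and all 16 milk genes (camera adjusted p = 1.33e-07, and adjusted p = 0.226 with an estimated correlation) were lower. Of the other lists called, the matrix-remodelling enzymes, inflammatory cytokines, resting fibroblast, epithelial-mesenchymal transition, contractile and pericyte genes were higher in CAF as sets, and the luminal, basal and keratinisation genes lower. The basal list was not called without the dimmest 30% of genes (adjusted p = 0.149), nor the contractile list without CSC replicate 2 (0.0971). The camera adjusted p of these lists over all arrays and genes lay between 9.30e-09 and 0.0354, and between 0.226 and 0.456 with an estimated correlation.

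Of 88 ligand-receptor pairs fixed in advance, 74 had both members measured, and 21 were split between CAF and CSC. The ligand was higher in CAF and the receptor in CSC for 14 of them, and the reverse held for 7. When receptors were reassigned to ligands at random in 10000 permutations, the median was 21 split pairs (95% of them between 15 and 26), and the one-sided permutation p was 0.536. Ligands higher in CAF included the fibroblast growth factors Fgf7 (4.60 ± 0.48) and Fgf10 (3.22 ± 0.14), whose receptor Fgfr2 (-0.79 ± 0.20) was higher in CSC. Fgfr2 differed by 0.036 (adjusted p = 0.841) without probe sets that can hybridise to related genes, and by -0.38 (adjusted p = 0.0730) with the mean of all its probe sets. It did not pass without CSC replicate 1 (-0.53, adjusted p = 0.0645). The CAF side also included Cxcl12 (4.57 ± 0.51), with its receptor Cxcr4 (-2.80 ± 0.55), and Jag1 (1.02 ± 0.17), with Notch1 (-2.32 ± 0.14). Cxcr4 was lower in CSC than in TEC (-2.18, limma adjusted p = 0.0154), as the leukocyte list was (median -2.13). Ligands higher in CSC included Pdgfa (-0.84 ± 0.20) and Pdgfc (-1.69 ± 0.31), with the receptor Pdgfra. They also included Tgfa (-2.63 ± 0.34), with Egfr (2.74 ± 0.48) (Tgfa -0.56 and Egfr 1.47 with the mean of all their probe sets), and Il1b (-6.02 ± 0.24), with Il1r1 (3.83 ± 0.41). Some CSC-side members are genes that leukocytes also express, such as Csf1r (-4.13 ± 0.27), Ccr2 (-3.90 ± 0.25) and Il1b, and Ptprc stood at 10.99 ± 0.53 in CSC against 7.76 ± 0.99 in CAF (mean log2 value ± SD, n = 2 and 3). No Hedgehog ligand was part of a split pair. Shh and Ihh lay under the lower quartile on every CAF and CSC array, which limits this result. Ihh (0.53, limma adjusted p = 0.00303) and Dhh (0.77, limma adjusted p = 0.00128) were higher in CAF, as their receptor Ptch1 was.

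**Figure D4:**
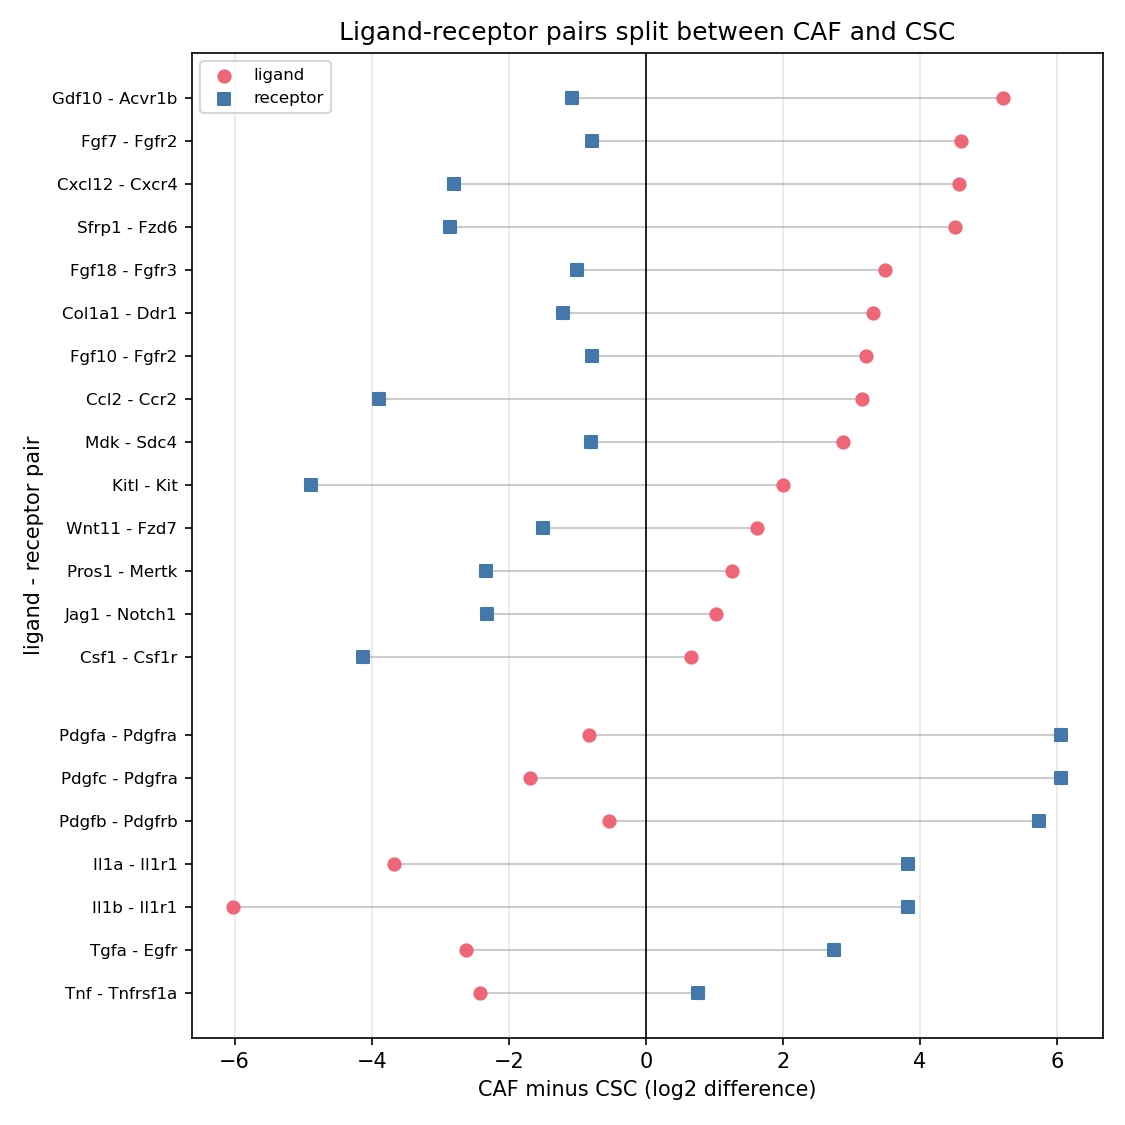
Log2 difference between CAF and CSC (x axis) of the ligand (circles) and the receptor (squares) of each of the 21 split pairs (y axis), limma estimates from 3 and 2 arrays. Ligands of the 14 upper pairs and receptors of the 7 lower pairs lie to the right of 0.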

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

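The settings that averaged arrays, left out 2 control arrays together or left out genes higher in tumour cells were chosen after seeing the data, and the others before. Between CAF and COF, 4309 genes passed. The count was 2638 at an adjusted p under 0.01 and 1030 with a difference of at least 1 on the log2 scale, both stricter by construction. It was 2291 (1282 higher and 1009 lower) without genes higher in CSC or TEC than in CAF, since fewer genes were counted. It was 1805 with the closest arrays averaged and 2807 without COF replicates 2 and 3, which leave fewer arrays, and 1805 and 2667 of these were among the 4309. Array weights gave 8632; the estimate of the weights did not converge and the cause was not tested. Between CSC and TEC, where 5786 passed, the count was 2377 with a difference of at least 1 and 3013 with only the 4 arrays. The same restriction to 2 groups gave 5686 genes between CAF and COF and 8691 between CAF and CSC. The median residual SD was 0.15 over all 10 arrays, 0.18 over CSC and TEC, 0.11 over CAF and COF and 0.12 over CAF and CSC, so counts fell where the spread was larger and rose where it was smaller. Between CAF and CSC, where 8247 passed, it was 3417 with a difference of at least 1. With each array centred on its median, 2937 genes were higher and 2939 lower in CSC than in TEC, against 3300 and 2486, and 4638 higher and 3681 lower in CAF than in CSC, against 4145 and 4102. Quantile normalization again gave 3893 and 4152 for the latter, and leaving out the dimmest 30% of genes 2584 and 3340. Leaving out each array in turn gave 2980 to 4316, 4417 to 6039 and 7059 to 7675 genes for the 3 contrasts. Where a single array of a group was left, it was assumed to vary like the other groups. The 6 fibroblast arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 4309 genes and the highest of the other 9 gave 0 in limma, with up to 368 genes at an unadjusted p under 0.05.

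Camera called 9, 17 and 19 lists in the contrasts CAF minus COF, CSC minus TEC and CAF minus CSC. With an estimated correlation it called 0 in each, with 1, 4 and 7 lists at an unadjusted p under 0.05; an estimated correlation allows for genes of a list that vary together. Fry called 13, 22 and 34, without comparing a list with other genes. Leaving out each array gave 9 to 10, 12 to 17 and 18 to 22 lists. Between CAF and CSC, fry reversed the direction of the adipocyte list (median 0.22, fry adjusted p = 7.81e-04 towards CSC) and of the mammary stem cell associated list (median 0.38, fry adjusted p = 0.00676 towards CSC); camera called neither. Their means and medians also differed in size or sign (means -0.10 and 0.08). The 21 split ligand-receptor pairs became 19 to 21 with each array left out, 17 without the dimmest 30% of genes and 14 with differences of at least 1.

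With the replicate number as a block, 3947, 5365 and 7813 genes passed and 9, 17 and 19 lists were called. Whether the numbers pair the arrays could not be settled. The deviations from the group mean of CAF and COF arrays of the same number had correlations across genes of 0.127, 0.00632 and -0.0824, and genes are not independent replicates. CAF and COF came from mice of different genotype, so these values cannot show a shared animal. The 2 arrays of CSC and of TEC deviate in mirror image. Their correlations, such as -0.057 for TEC replicate 1 with CSC replicate 1, thus cannot exclude a shared tumour. Of the genes named in the text, 54 of 56, 33 of 37 and 34 of 35 that passed did so without each array in turn. Over all settings, the call was kept in 2210 cases of a gene and a setting, 35 lost the call and 11 gained it. A gene that passed in neither fit counts as kept even where its sign changed. With the mean of all probe sets of a gene, which includes dimmer probe sets, further named genes moved by over 1.5 times with the call kept. Between CAF and COF these were Acta2 (1.67), Actn1 (1.97), Inhbb (1.37) and Notch2 (-0.53). Between CSC and TEC they were Axin2 (0.64), Pi16 (-2.01), Sox10 (0.96) and Zeb1 (-1.46), and also Btn1a1. Between CAF and CSC they were Axin2 (-1.15), Hgf (-1.78) and Ptch1 (1.17). Among named genes that passed in either fit, only Fgfr2 between CAF and CSC reversed. It went to 0.036 (adjusted p = 0.841) without probe sets ending in _x_at or _s_at, where another probe set stood for the gene. Differences in genes near the background, such as Shh, are limited by the signal of the arrays.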

Other observations

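The tests of COF replicate 3 as a mixture, of carry-over into CAF and of the arrays in which salivary genes lay, and the odds ratio of these genes, were chosen after the results were seen.

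Several Notch and receptor-signalling genes were lower in CAF than in COF. Of the Notch ligands, receptors and targets, 0 of 14 measured members rose, 5 fell and 9 did not pass (0 and 5 adjusted over the list alone), with a camera adjusted p of 0.0937. The receptors Notch1 (-2.18 ± 0.12) and Notch2 (-1.04 ± 0.14) and the target Hes1 (-1.09 ± 0.18) fell (log2 difference ± SE, n = 3 and 3). Of the Met and MAPK response genes, 2 of 13 measured members rose, 6 fell and 5 did not pass (3 and 6 adjusted over the list alone) (camera adjusted p = 0.131), and the feedback inhibitors of receptor tyrosine kinase signalling Spry4 (-1.41 ± 0.087) and Spred1 (-1.29 ± 0.10) fell. Of the immediate-early and dissociation stress genes, 3 of 20 measured members rose, 5 fell and 12 did not pass (3 and 5 adjusted over the list alone) (camera adjusted p = 0.146), with Egr2 (-1.04 ± 0.12) and Gadd45b (-1.55 ± 0.12) lower. Of the hypoxia and glycolysis genes, 5 of 18 measured members rose, 2 fell and 11 did not pass (8 and 2 adjusted over the list alone) (camera adjusted p = 0.118), with Ddit4 (1.24 ± 0.26) and Pgk1 (0.63 ± 0.10) higher. Of the pericyte and vascular smooth muscle genes, 4 of 11 measured members rose, 1 fell and 6 did not pass (4 and 1 adjusted over the list alone) (camera adjusted p = 0.151), with the pericyte gene Rgs5 (2.60 ± 0.17) higher. Of the Schwann cell genes, 0 of 10 measured members rose, 3 fell and 7 did not pass (0 and 3 adjusted over the list alone) (camera adjusted p = 0.410). None of 3 measured erythroid genes passed (camera adjusted p = 0.677). Fry, which does not compare a list with other genes, called the Notch list as lower in CAF (fry adjusted p = 0.00233). It also called the Met and MAPK list (4.01e-04) and the immediate-early list (0.00886) as lower. The hypoxia list (0.0176) and the pericyte list (4.01e-04) were called as higher by fry, and the Schwann cell list (0.0661) and erythroid list (0.298) were not called.

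Between CSC and TEC, some genes of vessels, muscle and skin were higher in TEC. Of the endothelial genes, 0 of 17 measured members were higher in CSC, 7 were lower and 10 did not pass (0 and 7 adjusted over the list alone), with camera adjusted p = 0.0159, and adjusted p = 0.365 with an estimated correlation. The list had an adjusted p of 0.0506 without TEC replicate 2 and 0.0739 without the dimmest 30% of genes, and its medians lay between 5.29 and 5.73 on these arrays. Of the skeletal muscle genes, 0 of 13 measured members were higher in CSC, 6 were lower and 7 did not pass (0 and 7 adjusted over the list alone), with camera adjusted p = 0.00908, and adjusted p = 0.350 with an estimated correlation. The medians of the muscle list were 5.42 and 5.41 in TEC, near the lower quartiles of these arrays (5.15 and 5.12). In CSC they were 4.63 and 4.62, under the lower quartiles (5.08 and 5.05), so the size of this difference depends on the background. Of the squamous and hair keratinisation genes, 3 of 26 measured members were higher in CSC, 9 were lower and 14 did not pass (3 and 9 adjusted over the list alone), with camera adjusted p = 0.0494, and adjusted p = 0.621 with an estimated correlation. The adjusted p of that list was 0.0557 to 0.384 when TEC replicate 2 or either CSC array was left out. It was 0.0579 with only the 4 arrays and 0.200 without the dimmest 30% of genes. With fry it was 0.0512. The hair keratin Krt25 (-4.10 ± 0.39) and the cornified envelope gene Sprr1a (-1.84 ± 0.35) were lower in CSC.

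COF replicate 3 lay between COF replicates 1 and 2 in 97.6% of the genes that differed by at least 1 on the log2 scale between those 2 arrays, 189 of them higher and 64 lower in replicate 2. Milk and proliferation genes were among them, with Csn2 at 5.84, 9.95 and 8.47 on replicates 1, 2 and 3. If replicate 3 held a mixture of both materials, 1 mixing share on the linear scale would account for genes of both directions. The median shares were 0.278 and 0.319, a difference of 0.0418 where up to 0.1 was allowed. CAF replicate 2, taken as a mixture of CAF replicates 1 and 3, also met this limit (0.085 and 0.162). So did CAF replicate 1, taken as a mixture of CAF replicates 2 and 3 (0.011 and 0.083). In these 2 cases only 72.1% and 49.3% of the genes lay between. The limit alone thus cannot tell a mixture from other causes, and shared or pooled material in COF replicate 3 stays possible. The labels do not say, no biological explanation was tested, and glands that differ along the same genes stay open.

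Epithelial, milk and leukocyte genes were higher in CAF than in COF, with list medians below those of the tumour cell arrays. Single genes departed from this. Of 10 measured granulocyte and mast cell genes, 2 were higher and 5 lower in CAF than in CSC. If CAF carried RNA with the CSC profile at 1 share, each pan-epithelial and milk gene would lie within 3 SE of the level that share predicts. Of all 33 genes, 11 (33.3%) lay further away at a median share of 1.33%, with the caseins Csn1s1, Csn2 and Csn3 above, but these lay near the top of the scale in CSC, where signals may saturate. Of the 11 genes off both ends of the scale (CSC mean up to 13.04 and COF mean of at least 5.51), 2 (18.2%), Lalba and Btn1a1, lay further away, both below. At least 20% was to count against this source. The share over all 33 genes exceeds that and the share over the 11 does not. Of the 11, 8 were at least 2 log2 units higher in CSC than in COF. Both genes that lay further away were among these 8, which exceeds 20%. The others, Xdh, Mfge8 and Stat5a, were predicted to change little. The limit to the 11 genes was set after both the result and the place of the caseins on the scale were seen. The verdict turned on which genes were counted, so 1 carry-over of the CSC profile cannot be told apart from others. With the TEC profile, 13 of 39 leukocyte genes (33.3%) lay further away, and 3 of the 8 off both ends (37.5%). Of these, the mast-cell genes Cpa3 and Cma1 lay above and needed shares of 35.9% and 34.2%, against a median share of 2.28%. Cd74 lay below, by -0.647 at an SE of 0.216, which is on the line of 3 SE. The values of Cpa3 and Cma1 argue against 1 uniform carry-over of the TEC profile as the source of the mast-cell genes. For the other leukocyte and macrophage genes off both ends the test does not decide, since these lay within 3 SE or on that line. Carry-over from other cells, such as mast cells or other epithelial cells, and expression in the CAF themselves may both contribute and were not tested.

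Of 7 genes of salivary secretion first noticed, 3 (Bpifa2, Amy1 and Chia1) were lower in CAF than COF and higher in CSC than TEC. If salivary tissue next to the gland had entered the COF and CSC preparations, 18 other salivary genes, not looked at before, would show both differences more often than other genes. Of these, 2 did, against 583 of 12369 other genes (4.71%, one-sided Fisher's exact p = 0.208). A p over 0.05 had been set to count against this source. With an odds ratio of 2.53 (95% CI 0.28 to 10.8), 18 genes are too few for that, and 3 of them lay on every array under the median lower quartile over the genes of the arrays, so the source cannot be told apart from others. Of all 25 salivary genes, 11 were at least 1 log2 unit higher in CSC replicate 2 than in CSC replicate 1, against 115 (0.928%) of all genes, and 4 of the 11 had not been looked at before. Salivary tissue in COF and CSC, glandular tissue in CSC replicate 2 alone and a difference between tumours may each contribute and stay open.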
